A study of Homo sapiens with 2 samples.

How the data were processed

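ATAC-seq was performed on 2 libraries of the C4-2 prostate cancer line, 1 with a control shRNA and 1 with an shRNA against WHSC1 (NSD2), and the control serves as reference per the labels. Groups were taken from the condition label of each sample; the deposited files call the control NSD2 wild type instead. The deposited files are 1 list of broad peaks per library, so the authors called peaks per library and did not pool. Per the submitters' processing notes, CASAVA 1.8.2, Bowtie2 2.2.9, SAMtools 1.9, Picard 1.101, MACS2 and ChIPseeker 1.22.1 were used with the GRCh38 build. The role and order of these tools, the MACS2 version, the Tn5 cut-site shift, the treatment of duplicate and mitochondrial reads and the peak calling options are not given in the sources used here. These steps can change the number, width and position of peaks, and duplicates or multi-mapping reads bear most on repeats.

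Each deposited peak has a fold enrichment, a ratio of pileup over the local background that the authors' peak caller estimated in the same library. It also has a −log10 p-value and a −log10 q-value from the same caller, and the deposited score equals the −log10 q-value times 10, truncated, for all 2010 control and 2418 knockdown peaks. These are each peak's own values from the authors. They were used to describe, rank or filter peaks, with the same −log10 q limits in both lists. Values of both lists are also given side by side, without scaling between the libraries. The background estimate of the closing section compares them between lists. The smallest −log10 q was 1.01 in the control and 1.02 in the knockdown. The files hold no read counts, so the depth of the libraries is unknown and no limit from read counts can be given. What limits precision is the number of peaks and the single library per group.

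Gene positions came from a RefSeq gene table of the same build (GRCh38.p14) with 59792 placed genes, of which 20037 protein-coding genes on chromosomes 1 to 22, X and Y were used. All 221 genes of the 13 fixed lists matched by symbol. The table gives gene starts and ends but no strand or transcripts. The comparison had been planned on promoters, within 3 kb of a transcription start site, and was therefore made on either end of a gene. Random gene lists had been planned with matching on promoter GC content, and were matched instead on the decile of protein-coding genes whose middle lies within 500 kb, since no genome sequence was used here. Coordinates are 1-based.

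Peaks were called shared with an overlap of at least 1 bp. The overlap and location expected by position alone came from 100 sets of peaks, each peak moved by a random 100 to 1000 kb. A gene had a peak if one lay within 3 kb of either end. Shares carry 95% exact Clopper-Pearson intervals, and a ratio of 2 counts the matching exact interval. These cover counting only, and neighbouring peaks and genes that share a peak are not independent. Lists were compared with 10000 random lists of equal size, as mid-percentiles (a tie counts 0.5). With 1 library per group no test between groups was made.

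Named genes followed a rule set, like the lists and most alternatives, before the data were examined. It took NSD2, the 10 genes with the highest fold enrichment among those with a peak in 1 library only (for each library), and the 5 highest by control fold among those with a peak in both. It added list members with a peak in exactly 1 library, and up to 4 per list with a peak in both. Its wording used promoter peaks, replaced as above. The values of 1 further gene are not reported here. Alternatives were a −log10 q of at least 5, equal numbers of peaks per list, chromosomes 1 to 22 and X only, an overlap of at least 50% of both peaks, sharing within 1 kb, merging within 500 bp, and a distance of 1 kb to a gene end. The scripts were tested on simulated data: of 300 peaks planted within 3 kb of a gene end all 300 were recovered, and of 1210 planted overlaps 1210. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.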

Results

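Open chromatin was mapped by ATAC-seq, in which a transposase cuts and tags accessible DNA, in C4-2 cells, a castration-resistant prostate cancer line derived from LNCaP. The study concerns WHSC1 (NSD2), a histone H3 methyltransferase, in prostate cancer and immune infiltration. One library came from cells with a control shRNA and 1 from cells with an shRNA against WHSC1, so there is no replicate in either group. No difference between the libraries can be set against a spread between replicates, no p-value is given, and every statement below compares these 2 libraries. The values are broad peaks on GRCh38, called by the authors separately in each library, each with the authors' fold enrichment over local background. Read depth is unknown. The intervals are 95% exact (Clopper-Pearson) intervals that cover the counting of peaks or genes only.

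The targeted gene had no peak in either library. NSD2 lies on chromosome 4 from 1871393 to 1982192, and neither list held a peak within the gene or within 3 kb of it. The nearest control peak was 280 kb away (chromosome 4, 2262150 to 2262438, 3.35-fold), and the nearest knockdown peak was 1178 kb away (693148 to 693366, 3.58-fold). An shRNA acts on the transcript, and the peak lists give no check of the knockdown.

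The first comparison asked how many accessible regions were called with and without the WHSC1 shRNA. The knockdown list held 2418 peaks and the control list 2010, a ratio of 1.20 (interval 1.13 to 1.28). The peaks covered 1210 kb in the knockdown and 982 kb in the control. Peaks were of similar width, with a median of 366.5 bp in the knockdown and 360.5 bp in the control. Most were weak: the median fold enrichment was 3.46 in the knockdown and 3.59 in the control. Only 239 knockdown peaks (9.88%) and 191 control peaks (9.50%) reached a −log10 q of 5.

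The strongest peaks of both libraries lay mostly in gene-free stretches, on contigs or beside genes with copies. No repeat annotation was used. The top peak in both was at 93470358 on chromosome 3, inside the centromere region, with 19.7-fold enrichment in the control and 20.5-fold in the knockdown. Another lay on chromosome 21 beside RNA45SN2, a copy of the ribosomal RNA precursor gene, with 13.1-fold enrichment in the control and 14.6-fold in the knockdown. All of the 20 strongest peaks of each list were overlapped by a peak of the other list. Only 1 of the 20 in each list lay within 3 kb of a protein-coding gene end, a peak between the near-identical genes TAF11L7 and TAF11L8. Reads from such copies can be assigned to the wrong place, so enrichment there is uncertain.

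The second comparison asked which regions were called in both libraries. A knockdown peak overlapped 1087 of the 2010 control peaks (54.1%, interval 51.9 to 56.3%), and a control peak overlapped 1080 of the 2418 knockdown peaks (44.7%, interval 42.7 to 46.7%). After moving peaks by random distances of 100 to 1000 kb, the mean overlap was 0.179% and 0.160%. This left 923 peaks called in the control only and 1338 called in the knockdown only. Peaks called in a single library were weaker, with a median −log10 q of 1.67 against 2.71 for shared peaks in the control, and 1.77 against 3.001 in the knockdown. At a −log10 q between 1 and 1.5, 24.0% of control peaks and 13.5% of knockdown peaks were shared. At 5 or more, 96.9% of control peaks (interval 93.3 to 98.8%) and 93.3% of knockdown peaks (interval 89.4 to 96.1%) were shared.

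**Figure D1:**
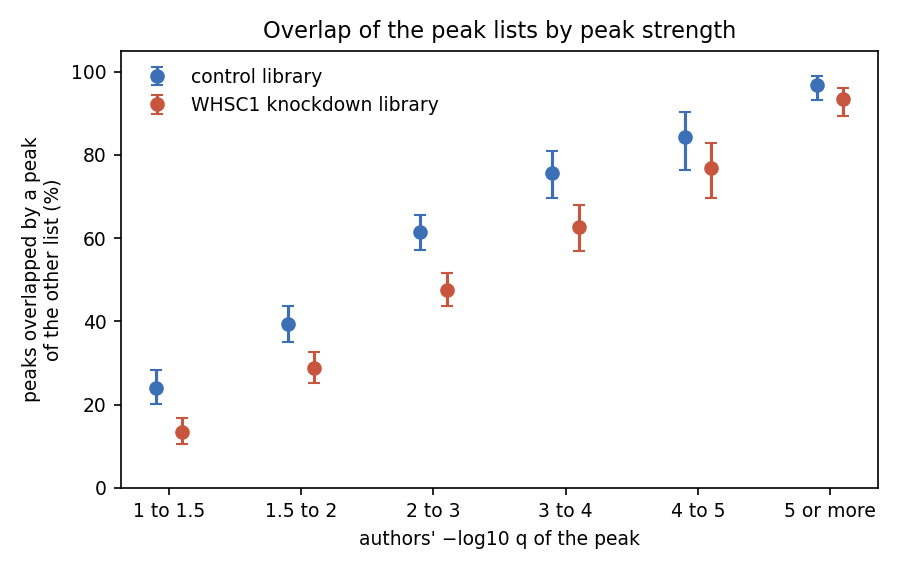
Share of each list's peaks (percent, vertical axis) that a peak of the other list overlaps by at least 1 bp, by the authors' −log10 q of the peak (horizontal axis), for the control library (blue) and the WHSC1 knockdown library (red). Points are shares and bars are 95% exact intervals for counting error; the share runs from 24.0% to 96.9% in the control and from 13.5% to 93.3% in the knockdown.

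Only 22 peaks with a −log10 q of 5 or more lacked any peak in the other list, and 3 of the 6 in the control and 4 of the 16 in the knockdown were within 3 kb of a gene end. The highest −log10 q lay outside genes in both: 15.9 in the control, on an unplaced contig (5.41-fold), and 46.1 in the knockdown, at 46386371 on chromosome 16 in a gene-free stretch (2.31-fold). The 6 of the control included a peak at UFM1, the gene of a ubiquitin-like modifier (chromosome 13, 38349541 to 38349855, 4.43-fold), and one at CDKN3, a cell cycle phosphatase (chromosome 14, 54396756 to 54396981, 4.73-fold). The 16 of the knockdown included a peak at GNG12, a G protein gamma subunit (chromosome 1, 67833183 to 67833427, 4.57-fold). Further knockdown peaks of this strength lay at ZNF143, a zinc finger transcription factor (4.07-fold), and between ATP6V1D and EIF2S1 (4.34-fold). UFM1 and ZNF143, like RNA45SN2 above, are outside the preset naming rule and were chosen after their values were seen. Of the other knockdown-only peaks of this strength, 3 were in a gene-free stretch of chromosome 17 and 2 on unplaced or unlocalised contigs.

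The third comparison asked where the peaks lie relative to genes. Peaks of both libraries were often at the ends of protein-coding genes: 1026 control peaks (51.0%, interval 48.8 to 53.3%) and 1212 knockdown peaks (50.1%, interval 48.1 to 52.1%) were within 3 kb of a gene end. Peaks moved at random by 100 to 1000 kb gave 5.95% and 6.03%. A further 16.2% of control and 17.6% of knockdown peaks lay inside genes, and 32.8% and 32.3% lay outside. The gene table gives no strand, so an end can be a 5′ or a 3′ end, and exons, introns and UTRs were not separated. Over all peaks, shared peaks were at gene ends more often than peaks of a single library, and the order turned when both lists were filtered. The share was 60.8% of shared control peaks (interval 57.8 to 63.7%) against 39.5% of control-only peaks (interval 36.4 to 42.8%). In the knockdown it was 61.1% of shared peaks (interval 58.1 to 64.0%) against 41.3% of knockdown-only peaks (interval 38.6 to 43.9%). With both lists filtered at a −log10 q of 5, it was 32.0% of 128 shared control peaks (interval 24.1 to 40.9%) against 68.3% of 63 control-only peaks (interval 55.3 to 79.4%), and 33.1% of 124 shared knockdown peaks (interval 24.9 to 42.1%) against 53.9% of 115 knockdown-only peaks (interval 44.4 to 63.2%).

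At the level of genes, 831 of 20037 protein-coding genes had a peak within 3 kb of an end in both libraries, 428 in the control only and 675 in the knockdown only. Either end counted, so a gene with a peak in both libraries need not have it at the same place. The lack of a peak in a list is the lack of a call at the authors' threshold, not a measured absence of accessibility. Genes with a peak in both had a median fold enrichment of 3.71 in the control and 3.66 in the knockdown. Genes with a peak in 1 library had medians of 3.51 in the control and 3.38 in the knockdown. With both lists filtered at a −log10 q of 5, 52 genes had a peak in the control only and 75 in the knockdown only. With such a peak in one list and no peak of any strength in the other, 3 genes remained for the control (LOC101929627, UFM1 and CDKN3) and 5 for the knockdown (among them GNG12, ZNF143, ATP6V1D and EIF2S1).

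Among the genes with a peak in the knockdown only, TMEM144 had the highest fold enrichment, 4.58, followed by GNG12 with 4.57. ABCE1, a ribosome recycling factor, and ANAPC10, a subunit of the anaphase-promoting complex, shared a 4.56-fold peak on chromosome 4 (145097943 to 145098305). SEPSECS, which makes selenocysteine on its tRNA, had a 4.42-fold peak. DTWD1 and FAM227B shared a 4.37-fold peak. ATP6V1D, a subunit of the vacuolar proton pump, and EIF2S1, the alpha subunit of translation initiation factor eIF2, shared a 4.34-fold peak on chromosome 14 (67359884 to 67360340). DNAJC3, an endoplasmic reticulum co-chaperone, also had a 4.34-fold peak, on chromosome 13 (95676862 to 95677096). The naming is by rank, and no theme was tested for these genes.

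Of the genes with a peak in the control only, LOC101929627 had the strongest, 5.50-fold, on chromosome 8. CDKN3 had a 4.73-fold peak, and PATL1, a factor of mRNA decay, a 4.69-fold peak. PDZD8, an endoplasmic reticulum tethering protein, had 4.67-fold enrichment, LIMS1, a focal adhesion protein, 4.62-fold, and EOLA1 4.61-fold. PSIP1, whose protein LEDGF binds methylated histone H3, had a 4.59-fold peak over its end on chromosome 9 (15510722 to 15511097). GAREM1 had 4.52-fold enrichment, WDR19, a component of ciliary transport, 4.45-fold, and WDFY2 4.44-fold. Among genes with a peak in both, the strongest in the control were copies of multigene families, whose reads are uncertain. The TAF11L7 and TAF11L8 peak had 11.2-fold enrichment in the control and 13.1-fold in the knockdown. FAM90A9 had 5.90-fold and 6.88-fold, and TAF11L5 with TAF11L6 5.62-fold and 5.87-fold.

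The fourth comparison took 13 gene lists fixed before the data were examined, chosen for the immune question and the prostate line. Of 19 MHC class I antigen presentation genes, only ERAP1, the peptidase that trims antigenic peptides, had a peak, with 3.60-fold enrichment in the control and 3.93-fold in the knockdown. The control peak of ERAP1 also lay within 3 kb of an end of LNPEP and of LOC124901030, so it cannot be assigned to ERAP1 alone. None of 10 MHC class II genes and none of 21 chemokine and cytokine genes had one in either library. Of 30 interferon response and nucleic acid sensing genes, 3 had a peak in the control and 2 in the knockdown. JAK2, a cytokine receptor kinase, had 3.42-fold enrichment in the control and 4.96-fold in the knockdown, and IFIH1, a sensor of viral RNA, 3.41-fold and 3.29-fold. The control peak of IFIH1 also lay within 3 kb of an end of GCA. RIGI, another RNA sensor, had a 3.32-fold peak in the control only (chromosome 9, 32526359 to 32526593, −log10 q 1.59).

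Of 20 androgen receptor and luminal prostate genes, ACP3, which encodes prostatic acid phosphatase, and STEAP2, a metalloreductase, had a peak in both libraries. NDRG1, a stress-response and androgen-regulated gene, had one in the control only (chromosome 8, 133297258 to 133297697, 3.85-fold). Of 19 cell cycle genes, CCNE2, CDK2 and AURKA had a peak in both and CDK6 in the control only (3.41-fold). The control peaks of CCNE2, CDK2 and AURKA also lay within 3 kb of an end of NDUFAF6, RAB5B and CSTF1, respectively. The CDK6 peak lay 2636 bp from the nearer end of the gene. Of 19 histone methylation genes, SETMAR had a peak in both (4.50-fold in the control, 3.90-fold in the knockdown). EED, a subunit of Polycomb repressive complex PRC2, had one in the control only (3.39-fold). Of 15 NF-kB and AP-1 genes, JUN had a peak in both (3.25-fold and 3.68-fold), and of 15 housekeeping genes PGK1 had one in the control only (4.15-fold). The other housekeeping genes, among them ACTB and GAPDH, had none in either library. The lack of a peak in the other lists therefore does not show closed chromatin at their genes. No gene among the 10 neuroendocrine, 12 epithelial-mesenchymal transition, 15 leukocyte and 16 stromal, endothelial and basal epithelial markers had a peak in either library.

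The lists were set against 10000 random lists of the same size, matched on local gene density, as a description of these libraries. For none of the 13 lists did the difference in members with a peak, knockdown minus control, fall below the 2.5th or above the 97.5th percentile. The difference was 0 or 1 gene fewer in the knockdown in each list, with percentiles from 10.6 for housekeeping genes to 47.3 for MHC class II genes. The cell cycle list, with 4 of 19 genes in the control, stood at the 98.1st percentile of the number with a peak, and at the 88.6th in the knockdown with 3. With peaks filtered at a −log10 q of 5 in both lists, the interferon list turned to 1 gene more in the knockdown, JAK2. Only 6.28% of protein-coding genes had a peak in the control and 7.52% in the knockdown, and random lists of these sizes held a mean of 0.146 to 1.83 such genes in the control.

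The fifth comparison was across chromosomes. Peaks at gene ends were most frequent on chromosomes 3, 5 and 8 and nearly missing from the gene-rich chromosomes 17, 19 and 22, in both libraries. Chromosomes 21 and X, which are less gene-dense, were low too, with 0 and 2 of 239 genes (0.837%) on chromosome 21 and 1.77% of 848 genes in each library on X. Chromosome 11, with a higher median gene density than chromosome 22 (19 against 17 neighbours within 500 kb), had 6.38% and 7.15%. On chromosome 8, 15.7% of 715 genes had a peak in both the control and the knockdown (interval 13.1 to 18.5%). On chromosome 3 the shares were 15.4% and 15.0%, and on chromosome 5 13.5% and 16.0%. On chromosome 19, 1 of 1451 genes had a peak in the control (0.0689%, interval 0.00174 to 0.383%) and 12 in the knockdown (0.827%, interval 0.428 to 1.44%). On chromosome 17, 0.770% and 0.599% of 1169 genes had one. None of 451 genes on chromosome 22 had one in either library, which allows a share of up to 0.815%.

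**Figure D2:**
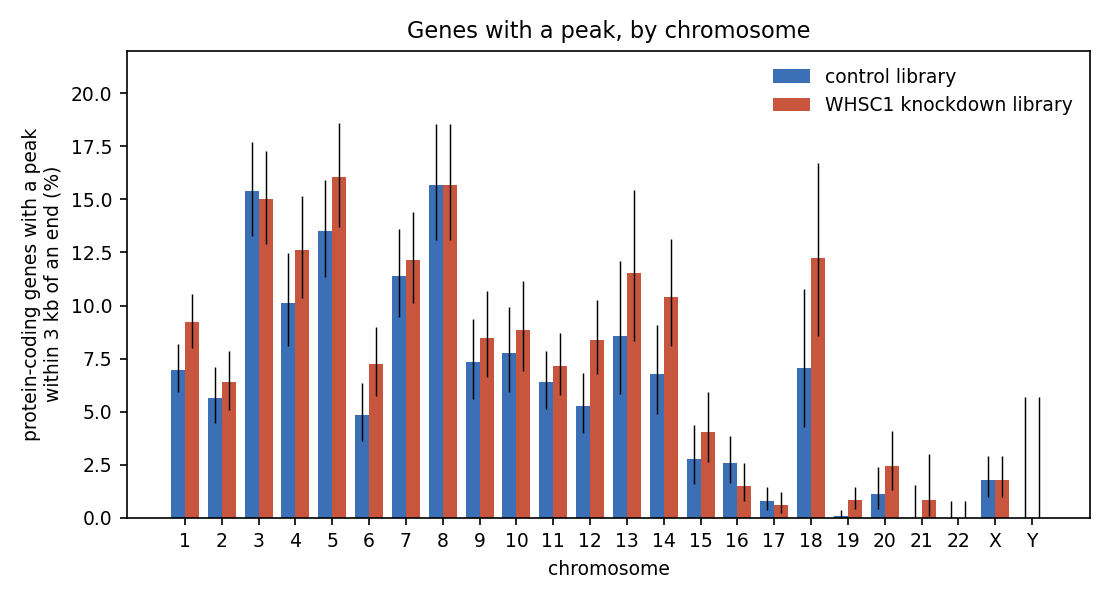
Share of protein-coding genes (percent, vertical axis) with a peak within 3 kb of an end, by chromosome (horizontal axis), in the control (blue) and WHSC1 knockdown (red) libraries, with 95% exact intervals for counting error as black lines. Chromosomes 3, 5 and 8 stand between 13.5% and 16.0%, and chromosomes 17, 19 and 22 below 1%.

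Across the genome the share of genes with a peak was lower where genes were dense, though not in every step. In the decile with the fewest protein-coding neighbours within 500 kb (0 to 3), 11.6% of genes had a peak in the control (interval 10.3 to 13.1%) and 12.8% in the knockdown (interval 11.3 to 14.3%). In the densest decile (35 to 75 neighbours) the shares were 1.25% (interval 0.809 to 1.84%) and 1.85% (interval 1.30 to 2.54%). The highest shares were in the second decile (3 to 5 neighbours), 14.4% (interval 12.9 to 16.0%) and 16.1% (interval 14.5 to 17.8%), and the lowest in the ninth, 0.998% and 1.70%. The knockdown shares were above the control shares in all 10 deciles. The knockdown list was also the longer (2418 against 2010 peaks), which by itself raises such shares.

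**Figure D3:**
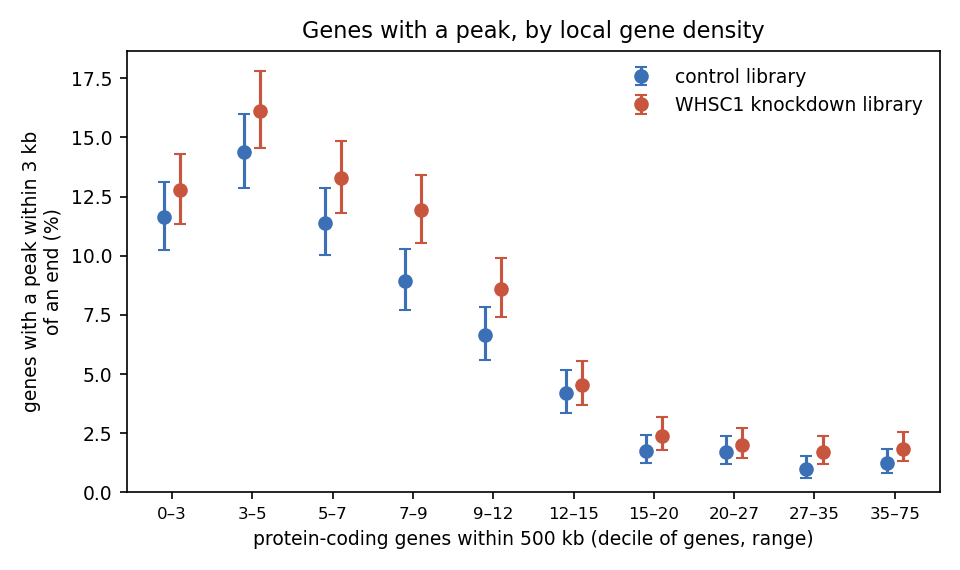
Share of protein-coding genes (percent, vertical axis) with a peak within 3 kb of an end, in 10 deciles of the number of protein-coding genes within 500 kb (horizontal axis, range of each decile), for the control (blue) and WHSC1 knockdown (red) libraries. Points are shares and bars 95% exact intervals for counting error; the control has 11.6% in the sparsest, 14.4% in the next and 1.25% in the densest decile.

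Among single chromosomes the ratio of knockdown to control peaks was 1.02 on chromosome 8 (202 against 199 peaks) and 1.44 on chromosome 6 (104 against 72). It was lowest on chromosome 16, 0.767 (23 against 30), and highest on chromosome 19, 2.60 (13 against 5), followed by chromosome 21 with 1.86 (13 against 7), all on few peaks. It was 1.73 on chromosome 17 (71 against 41), where most peaks lay in a gene-free stretch over the centromere. That stretch, from 22705637 to 26981691, held 56 knockdown and 31 control peaks, with median fold enrichments of 4.17 and 4.38.

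**Figure D4:**
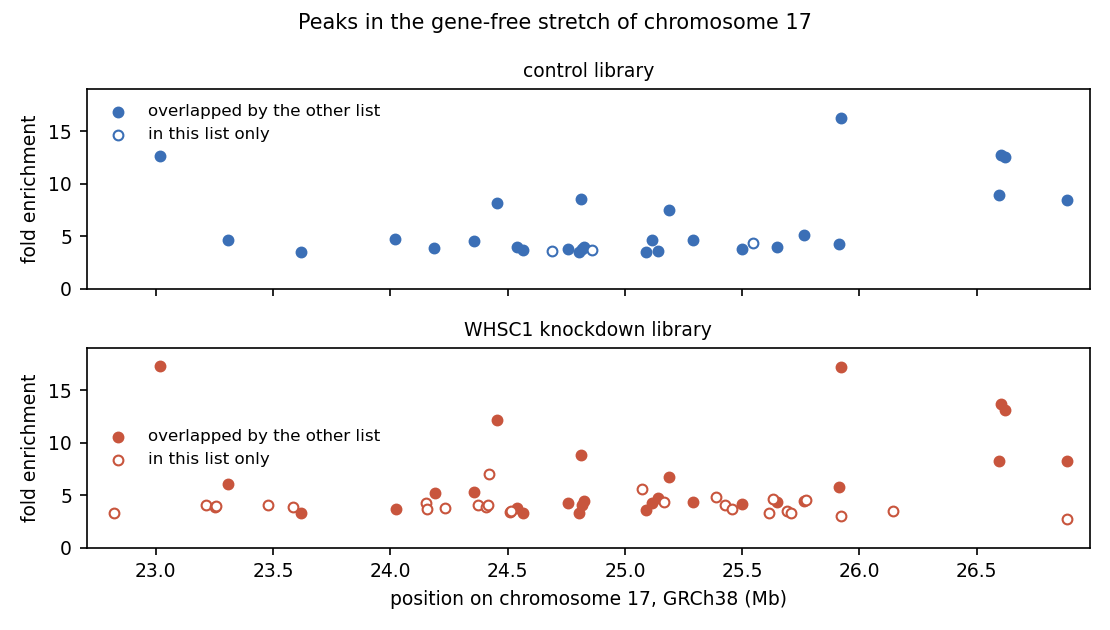
Position in Mb (horizontal axis, GRCh38) and the authors' fold enrichment (vertical axis) of the peaks in the gene-free stretch of chromosome 17, for the control (top, 31 peaks) and WHSC1 knockdown (bottom, 56 peaks) libraries. Filled points are overlapped by a peak of the other list and open points are not; 28 knockdown and 3 control peaks are open.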

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

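The 2 results here come from peaks outside the gene comparisons and stand above the control library, and the tests of unshared peaks and of their q values were chosen only after the result was seen. The knockdown list held 79 peaks on unplaced and unlocalised contigs, and the control list 62 (ratio 1.27, interval 0.902 to 1.81). Outside contigs and gene-free stretches the ratio was 1.19 (interval 1.12 to 1.27), so the contigs do not stand apart from the rest of the lists.

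The other is the stretch of chromosome 17 from 22705637 to 26981691, which holds no annotated gene of any kind and spans the assembled centromere. The knockdown list held 56 peaks there and the control list 31, a ratio of 1.81 (interval 1.14 to 2.90), against 1.19 (interval 1.12 to 1.27) for all other peaks. Of the 31 control peaks, 28 were overlapped by a knockdown peak, while 28 of the 56 knockdown peaks had no control peak, against 55.3% of all knockdown peaks. The peaks covered 67.4 kb in the knockdown and 37.4 kb in the control.

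Chance calls at the threshold stay open. At the unshared share of knockdown peaks elsewhere in the same interval of −log10 q, 20.8 of the 56 peaks would be unshared (central 95% of draws 15 to 27). The 28 observed lie just above, but the stretch was picked for its excess, and its peaks are not independent. The draws therefore cannot decide the question. The counting interval of the 28, 20.3 to 35.7, reaches into that range, but the draws already hold counting error, so this overlap adds nothing. These 28 had a median −log10 q of 2.87 (bootstrap interval 2.34 to 3.12), above the 1.75 of the other 1310 knockdown-only peaks. Of all knockdown peaks between 2 and 3, 47.6% had a control partner, so this median does not exclude such calls. The upper quartile of the 28 was 3.39, and 3 of them reached 5 or more. Of all knockdown peaks, 62.6% between 3 and 4 and 93.3% at 5 or more had a control partner. Repeat sequence in general stays open too. In the other gene-free stretches of at least 1 Mb the ratio was 1.19 (56 against 47 peaks, interval 0.794 to 1.79). Its upper limit lies just under 1.81, the bound set beforehand, but that bound left out the counting interval of the chromosome 17 ratio itself, which overlaps. A change with the knockdown at this centromere may be another explanation, which 1 library per group cannot test.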

How the results depend on the processing

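No paired analysis was possible because each group has 1 library, and no library could be left out. Single-start-site alternatives were not run, since the gene table holds no strand. The ratio of peak numbers stayed between 1.19 and 1.25 under its 4 alternatives, and merging within 500 bp joined no peaks, so that setting tests nothing. The settings of strong peaks against the full other list, of peaks without contigs and gene-free stretches (the ratio of 1.19), and of peaks anywhere in a listed gene, as well as the difference between shared and single-library peaks and the joining of the 13 lists, were chosen after seeing the data. The share of control peaks overlapped, 54.1%, was 67.0% with a −log10 q of at least 5 in both lists, 51.3% with equal numbers of peaks, 41.9% with an overlap of at least 50% of both peaks, and 96.9% for strong peaks against the full other list. The share of knockdown peaks overlapped, 44.7%, was 51.9%, 51.0%, 34.8% and 93.3% under the same settings. Control and knockdown shares near a gene end, 51.0% and 50.1%, were 44.0% and 43.1% for −log10 q of at least 5, and the knockdown share was 47.8% within 1 kb. For control-only peaks the 39.5% became 68.3% with both lists filtered and 45.1% with 50% overlaps. For knockdown-only peaks the 41.3% became 53.9%, 45.2%, and 38.3% within 1 kb. The gene-end share of shared peaks minus that of single-library peaks, 21.3 percentage points in the control and 19.9 in the knockdown, reversed to -36.2 and -20.8 with both lists filtered, was 14.1 and 14.0 with 50% overlaps, and 20.1 to 21.5 with the 1 kb settings. Filtering both lists makes strong peaks with a weak partner count as peaks of 1 library, by construction; any other cause of the reversal was not tested. Within each of 5 intervals of −log10 q below 5, with sharing judged on the full lists, shared peaks had the higher gene-end share in both libraries, the thinnest interval holding 19 control-only peaks. At 5 or more the control went the other way, on few peaks (81 of 185 shared against 3 of 6 control-only peaks), and the knockdown did not (99 of 223 shared against 4 of 16 knockdown-only peaks). Genes with a peak in the control only numbered 52 instead of 428 and in the knockdown only 75 instead of 675 with both lists filtered, 465 and 533 with equal numbers of peaks, and 3 and 5 with a strong peak in one list and none in the other. Of the differences per gene list, 2 changed sign, both with the filter: the interferon list went from -1 to 1 and all 13 lists together from -5 to 1, where 1 gene was left. The other settings left each single list within 1 gene of its main value, and the joined lists at -5 or, with equal numbers of peaks, at -7. Unknown depth limits the rest: weak sites may pass the threshold in one library and miss it in the other, as 93.3% of strong and 44.7% of all knockdown peaks had a partner.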

Other observations

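The gene families, the tests in this part and the joining of the 13 lists into 1 were chosen after the peak lists were seen; the 13 lists themselves were fixed before. Some gene families, picked by symbol, were set against random lists. Of 35 aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, 9 had a peak in the control and 7 in the knockdown, against 2.46 and 2.97 expected from random lists matched on gene density (percentiles 99.97 and 98.6). These genes rest on 8 and 6 peaks, as HARS1 and HARS2 share one. LARS1 (4.75-fold in the control, 3.94-fold in the knockdown) and WARS2 (4.15-fold and 5.36-fold) had one in both. The choice by symbol left out FARSB, a synthetase subunit gene with a peak in both (4.54-fold and 3.20-fold). The counts are therefore those of the 35 picked genes, not of every synthetase gene. DNAJ co-chaperones had a peak in 8 of 45 genes in each library, 6 of them shared (expected 3.12 and 3.72) and resting on 7 peaks in each, DNAJB9 among them with 4.74-fold and 4.05-fold. Mitochondrial ribosomal protein genes had 12 of 77 in the control and 7 in the knockdown (expected 4.26 and 5.18), a difference at percentile 0.155. The peaks of the control-only genes of this family had a −log10 q of 1.12 to 3.32. Of control peaks below 2, at most 39.4% in an interval had a knockdown partner. The peaks of MRPL18 (3.32) and MRPL17 (3.29) were stronger, and 75.5% of control peaks between 3 and 4 had a partner. Threshold calls may thus account for part of this difference, as for most single-library peaks (at 5 or more at least 93.3% of either list had a partner). Olfactory receptor genes had 2 and 3 of 392 (expected 9.05 and 11.6). None of 152 genes with symbols starting KRT (expected 1.95 and 2.94) and none of 39 beta-defensin genes (expected 1.05 and 1.32) had one in either library. Of the other families tried, cytosolic ribosomal protein genes had 6 and 10 of 84 (expected 4.55 and 5.65), NADH dehydrogenase genes 4 and 5 of 46 (expected 2.87 and 3.45), ZNF zinc finger genes 27 and 36 of 517 (expected 21.4 and 26.5), proteasome genes 1 and 1 of 50 (expected 2.58 and 3.20), and E2 ubiquitin-conjugating enzymes 0 and 1 of 36 (expected 2.34 and 2.73).

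Clustered histone genes, which are transcribed in S phase, had no peak near an end in the control and 7 of 74 had one in the knockdown (9.46%, interval 3.89 to 18.5%). These 7 genes rest on 4 peaks. On chromosome 6 the pairs H2BC4 with H2AC6 (26123405 to 26124307, 3.30-fold), H2BC11 with H2AC11 (27132522 to 27133051, 3.45-fold) and H2BC12 with H2AC12 (27146789 to 27147667, 3.18-fold) each shared a peak, and H4C16 on chromosome 12 had the other (2.87-fold). Their −log10 q lay between 1.35 and 2.36, and 47.6% of knockdown peaks between 2 and 3, and fewer below, had a control partner. The difference stood at percentile 99.995 of random lists, which do not keep the clustering of these genes, so it overstates how far the family stands apart. Over all 13 fixed lists together, 15 of 221 genes had a peak in the control and 10 in the knockdown, with 5 in the control only (RIGI, NDRG1, EED, CDK6 and PGK1) and none in the knockdown only, a difference at percentile 1.40. It stayed at -5 genes within 1 kb of a gene end and for peaks anywhere in a gene. In the latter setting 6 genes had a peak in the control only and 1 in the knockdown only. With equal numbers of peaks it was -7 (8 in the knockdown against 15 in the control). It reversed with both lists filtered at a −log10 q of 5, where 1 gene was left in the knockdown and 0 in the control. The peaks of RIGI, EED and CDK6 had a −log10 q of only 1.59, 1.39 and 1.71. Those of NDRG1 and PGK1 had 3.82 and 2.74, in intervals where 75.5% and 61.4% of control peaks had a partner.

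The peaks called in 1 library only, and the larger knockdown list, have technical explanations that the tables leave standing. Peaks near the calling threshold may account for most: at a −log10 q of 5 or more, at least 93.3% of the peaks of either list had a partner. The background pileup implied by fold and p, assuming the peak caller's usual formulas, had a median of 3.12 over the 1419 control peaks with a −log10 p below 7 and of 3.56 over the 1687 such knockdown peaks. A deeper knockdown library, in which weaker sites pass the threshold, could give that ratio of 1.14 (bootstrap interval 1.12 to 1.16). A higher background at equal depth could give it too, and the lists do not tell these apart. The medians come from different sets of peaks, and the interval covers the draw of peaks only. Whether those formulas hold for the deposited broad peaks was not checked. An effect of WHSC1 knockdown on the 16 strong knockdown-only peaks stays open, as no replicate list shows how many such peaks 2 libraries of one condition would give. Of these 16, only 4 lay within 3 kb of a protein-coding gene end. Another 3 lay in the gene-free stretch of chromosome 17 and 2 on unplaced or unlocalised contigs, where reads can be assigned to the wrong place.

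The scarcity of peaks at genes in gene-dense regions was in both libraries. It is not an effect of the knockdown, since in the control alone the sparsest decile had 9.32 times the share of the densest. Copy number of whole chromosomes is excluded as the whole cause, because the genes of a chromosome below its median density had a higher share than those above it in 14 of 15 chromosomes in the control and 15 of 16 in the knockdown. The median ratio was 2.81 in the control and 2.33 in the knockdown, over chromosomes with at least 20 genes with a peak. Chromosomes with fewer, among them 17, 19, 21, 22 and X, were left out in both libraries. The comparison therefore does not bear on their low shares. Loss of GC-rich fragments could give such a gradient (6.92 times in the knockdown from sparsest to densest decile) but could not be tested, because GC content was not measured here.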
